A study of Mus musculus with 2 samples.

How the data were processed

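DN1 cells were purified by flow cytometry from embryonic thymus and profiled with 10x 3' v3 chemistry, per the labels' protocols, with 1 library for E15.5_DN1 and 1 for E19.5_DN1. The extraction label describes a lysis step that yields nuclei, so whether whole cells or nuclei were loaded is not settled here. The deposited values are whole-number UMI counts per gene and barcode. Reads were processed with Cell Ranger 3.0.2 and STAR on GRCm38, per the submitters' processing notes. The settings used to call cells are not given in the sources used here. The table includes reporter rows, and the genes of the T-cell receptor chains were not analysed here. Results of 1 locus and its reporter are not reported here. Of its columns, 0 are tied to a library by any label, so the planned stage comparisons were not run and the pooled plan for that case was followed.

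Barcodes with fewer than 500 genes or over 10% mitochondrial UMIs were removed, 35 of suffix 1 and 507 of suffix 2. Scrublet, run per suffix in scanpy 1.11.5, called 99 doublets (1.80% of those that passed), 9 in suffix 1 (0.419%) and 90 in suffix 2 (2.67%), and these were removed. The low rate in suffix 1 leaves doublets there possible. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 components were used with 15 neighbours, and Leiden clustering at resolution 1 (leidenalg 0.10.2) gave 23 clusters. Both suffixes were clustered together without integration. The reporter rows were left out of the variable genes, a choice made after the table was seen. Kept cells had between 713 and 113167 UMIs, with 39797350 UMIs in suffix 1 and 59239093 in suffix 2.

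Clusters were named from 17 marker lists. A cluster took the list with the highest median fold over other cells, at least 1.5, with at least 3 detected markers. That scoring rule was set after the data were seen. Cluster 3 was set to unnamed by a separate rule, as Krt8 was among its leading genes while nearly all its barcodes held Gzma. Of the other clusters, 1 of low UMI count stayed unnamed. Gene lists, markers, filters, the rule for named genes and the first set of alternatives were fixed before the data were examined. The named genes are the reporter locus genes, the 3 genes with the highest fold in each cluster among those of at least 50 CPM, and the 4 most abundant members of each list. Cd163l1, Zbtb16, Mki67, Gzmb, Arpp21, Hba-a1, Kit and Flt3 are named beyond that rule, chosen after their values were seen.

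UMIs were summed per class and given as CPM with exact Poisson intervals, ratios with conditional exact intervals, and shares with Clopper-Pearson intervals. A count of 0 against a detected gene was set at 3 counts. List medians use members with at least 20 UMIs, and the pairs of classes compared were chosen after the classes were named. For shares of cells with a UMI, cells were thinned to 6970 UMIs, the 10th percentile, which left out 542 cells. The functions were tested on simulated data for the comparison of ILC2-like with early T progenitor-like cells. Of intervals for 9563 genes, 200 of them changed, 95.2% held the true value. The median error of the changed genes was 0.048 on the log2 scale. Of 100 unchanged lists, 4 fell beyond the outer 5% of random lists, and all 450 simulated cells received their own name. The simulated counts were Poisson draws from fixed profiles, and the simulated cells were drawn from the profiles of the named classes. These results therefore check the functions only, and leave untested the further variation between real cells and the names themselves. Alternatives covered cell filters, doublets, clustering, scaling, thinning and list filters. A first comparison of Rora with other genes, all paired with Zbtb16, put Rora at percentile 99.1. It was set aside because Zbtb16 had been picked for Rora, and each gene was given its own best partner among 3740 genes instead. For the same reason the interval for Zbtb16 was widened for those 3740 genes, and an unwidened ratio of 11.97 (3.01 to 41.0) was set aside. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.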

Results

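Single-cell RNA sequencing was run on double-negative 1 (DN1) cells sorted from the embryonic thymus of mice that carry fluorescent or surface reporters. The reporters described here mark Id2, Gata3, Rora and Bcl11b, transcription factor genes used to tell T cell from innate lymphoid cell (ILC) development. The labels name 2 samples, E15.5_DN1 and E19.5_DN1, with 1 library each. The deposited count table held cell barcodes in 2 sets, suffix 1 with 2182 barcodes and suffix 2 with 3875. No label or column ties a suffix to a stage, so stages were not compared and all barcodes were treated as 1 pooled sample. Values within each suffix are given beside pooled ones for some gene lists, genes and reporters. After filters 5416 cells remained, 2138 of suffix 1 and 3278 of suffix 2, with 99036443 unique molecular identifiers (UMIs) in total. The median was 14858 UMIs per cell in suffix 1 and 13687.5 in suffix 2. There are no replicates, so no test of a difference between groups was run. The 95% intervals of values, shares and ratios in the report cover counting error only, and that of a list median covers the spread of its members.

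The cells fell into ILC2-like, NK/ILC1-like and early T progenitor-like classes and several smaller ones, which addresses which lineages a DN1 sort of the embryonic thymus holds. ILC2-like cells were 1733 of the 5416 kept cells (interval 30.8 to 33.3%), NK/ILC1-like cells 23.9% (1297 cells, 22.8 to 25.1%) and early T progenitor-like cells 21.9% (1186 cells). The remaining named classes were gamma-delta T-like (216 cells, 3.99%), DN2/DN3 T-committed-like (202 cells, 3.73%), alpha-beta thymocyte-like (84 cells, 1.55%), mast cell- or basophil-like (71 cells, 1.31%) and B lineage-like (5 cells, 0.0923%). A further 622 cells (11.5%) stayed unnamed, 555 of them in cluster 3, which is described apart. Without cluster 3, ILC2-like cells were 15.52% of suffix 1 and 45.4% of suffix 2, and NK/ILC1-like cells 46.6% and 17.0%. Early T progenitor-like cells were 23.9% of suffix 1 and 24.6% of suffix 2. DN2/DN3-like cells were 9.09% and 1.77%, and gamma-delta T-like cells 1.26% and 5.98%. The sort sets these shares, and other clusterings moved most of them. Gamma-delta T-like cells went to 9.75% with 4000 variable genes and 14.5% with cluster 3 removed first, and DN2/DN3-like cells to 1.64% at resolution 2.

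The clusters within a class had different leading genes. The largest ILC2-like cluster, cluster 1, was led by Ly6c1 (86.6 CPM, UMIs scaled to the total of the class or cluster, against 3.00 CPM in other cells), Pard3 and Il1rl1, the receptor for interleukin 33, and took 883 of its 889 cells from suffix 2. Cluster 7, also ILC2-like, was led by Slc38a4 and Gclc (512 against 83.4 CPM). The smaller ILC2-like cluster 15 was led by the amino acid transporter gene Slc38a5 (459 against 3.44 CPM) and Cxcl3. The NK/ILC1-like cells split by suffix. Cluster 4, led by the granzyme gene Gzmc (3740 against 78.6 CPM), held 424 cells of suffix 2 and 13 of suffix 1. Cluster 5, led by Ccl4 and Dll1, held 364 cells of suffix 1 and 51 of suffix 2. A cluster drawn from 1 suffix may reflect that library. Interferon response genes led the ILC2-like cluster 21 (Ifit1, 1252 against 15.4 CPM) and the early T progenitor-like cluster 22 (Rsad2, 488 against 6.82 CPM). The globin gene Hbb-bs led cluster 8, and Ly6c2, a marker fixed for another class, was among the leading genes of cluster 4. Clusters 4, 15, 21 and 22 had none of their own class's markers among their 10 leading genes, and clusters 14 and 20 had more markers of other classes there than of their own.

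ILC2-like and early T progenitor-like cells were compared to ask how the innate lymphoid programme differs from that of uncommitted progenitors. The stem and progenitor regulators were lower in ILC2-like cells, with a median log2 ratio of -6.55 (-4.79 within suffix 1, -6.60 within suffix 2) and 15 of 19 measured members below -1. Spi1, which encodes PU.1, had 0.562 CPM in ILC2-like and 140 CPM in early T progenitor-like cells, and Bcl11a 3.03 and 147 CPM. Of the list, 12 members are markers that named the classes, and without them the median was -6.17. Notch pathway genes were lower, with a median of -1.86 over 11 members and 8 below -1. Notch1 had 21.2 CPM in ILC2-like and 140 CPM in early T progenitor-like cells, a log2 ratio of -2.73 (-2.86 to -2.59). MHC class I genes were higher in ILC2-like cells, with a median of 1.49, of 0.74 within suffix 1 and of 1.61 within suffix 2. H2-D1 had 1668 against 337 CPM, while Psmb8, an immunoproteasome subunit gene, went the other way with 633 against 793 CPM. Homing and adhesion receptors had a median of 3.02 (1.80 and 3.15 within the suffixes) and immediate early genes one of 1.45. The immediate early gene Junb had 613 against 80.9 CPM. The most abundant member of each of these lists was lower, Itga4 with 239.8 against 370.1 CPM and the heat shock gene Hsp90aa1 with 620.5 against 1674 CPM. The interleukin 7 receptor gene Il7r, from the cytokine receptor list, had 624 against 27.3 CPM. The interferon response list had a median of 0.85 over both suffixes, but -0.86 within suffix 1 and 0.79 within suffix 2, so its direction did not hold within suffixes.

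NK/ILC1-like and ILC2-like cells were compared to set apart the innate lymphoid classes. Cytotoxic and type 1 genes had a median log2 ratio of 6.59 (5.35 within suffix 1, 7.59 within suffix 2) with 19 of 20 members above 1. Type 2 effector genes had one of -2.61 (-2.05 and -3.85) with 13 of 14 below -1. These lists share 15 and 13 members with the markers of the classes and so largely restate the names, and without them the cytotoxic median was 8.14, and the 1 type 2 gene left had a log2 ratio of -1.31. The chemokine genes Xcl1 (1865 against 3.54 CPM) and Ccl5 (1425 against 24.3 CPM) were higher in NK/ILC1-like cells. The costimulatory receptor gene Icos was lower, with 54.7 against 640 CPM. Cytokine receptors had a median of -0.85, with -0.88 within suffix 1 and -0.65 within suffix 2, but Ifngr1 was higher with 295 against 209 CPM. Glycolysis genes had a median of -0.60, with -0.68 and -0.62 within the suffixes. Aldoa, which encodes an aldolase, had 495 against 1087 CPM. The interferon response median was -0.20 over both suffixes but 0.98 within suffix 1 and 0.45 within suffix 2, so no direction is given for it.

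DN2/DN3-like and early T progenitor-like cells were compared to describe the step to T commitment. T-cell receptor and recombination genes were higher, with a median log2 ratio of 2.86 (3.67 within suffix 1, 1.43 within suffix 2) and 8 of 10 members above 1. Of these, 9 are markers of the classes, and the 1 gene left had a log2 ratio of 0.50. Cd3g had 1212 against 42.6 CPM, but it also had 1428 CPM in NK/ILC1-like and 801 CPM in ILC2-like cells. Its level is thus not particular to T commitment here. Stem and progenitor regulators were lower, with a median of -1.89 and 17 of 19 members below -1. Most of that list, Spi1 and Lyl1 included, are markers that named the early T progenitor class, so its direction partly restates the name. Spi1 had 37.8 against 140 CPM, whereas Lyl1 had 99.7 against 129 CPM, a log2 ratio of -0.37 (-0.48 to -0.27). The interferon response list had a median of -1.78, with -1.27 within suffix 1 and -1.12 within suffix 2. Isg15 had 29.0 against 104 CPM, but Bst2 293 against 287 CPM. Immediate early genes had a median of -1.05, and Jun had 230 against 542 CPM, but Hsp90aa1, the most abundant member, had 2061 against 1674 CPM. The granzyme gene Gzma had 1529 CPM in DN2/DN3-like cells against 144 CPM. Suffix 1 held 144 of the 202 DN2/DN3-like cells but 379 of the 1186 early T progenitor-like cells. Over kept cells outside cluster 3, Jun had 320 CPM in suffix 1 and 508 CPM in suffix 2, and Gzma 1534 and 300 CPM. The pooled values of these genes may therefore hold a difference between suffixes. Notch1 was 0.27 higher within suffix 1 and had a log2 ratio of -0.33 within suffix 2, so no direction is given for it. DN2/DN3-like cells form 1 cluster, cluster 11, led by Fbp1, Khdc1a and Fam169b. Its 10 leading genes hold none of the 14 DN2/DN3 markers and Arpp21, an alpha-beta thymocyte marker, so the name rests on a median fold of 2.02 over the markers.

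Gamma-delta T-like cells differed from ILC2-like cells in T-lineage genes. The T-lineage regulators had a median log2 ratio of 0.92 over 16 members, with 0.89 within suffix 1 and 0.97 within suffix 2, but 0.33 to 0.52 under 3 other clusterings. Tcf7, which encodes TCF-1, had 331 against 52.7 CPM and Myb 117 against 8.82 CPM. Cd3d had 1118 against 43.4 CPM. Maf differed less, with 347 against 248 CPM, a log2 ratio of 0.48 (0.39 to 0.57), but -0.36 within suffix 1. The genes of the T-cell receptor chains were not analysed here, so the name rests on 4 of 16 listed markers. Sox13 (133 against 4.49 CPM) and Blk (233 against 1.86 CPM) were higher, while Icos (40.6 against 640 CPM) and Cd163l1 (316 against 349 CPM) were not. Suffix 1 held only 20 of these cells. The gamma-delta T-like cluster 20 was led by Il17a with 123 CPM against 0.589 in other cells. Alpha-beta thymocyte-like cells, all 84 from suffix 2, were led by Cd8b1 with 1153 CPM.

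Within the ILC2-like class, clusters 7 and 1 were compared among cells of suffix 2. Cell cycle genes were higher in cluster 7, with median log2 ratios of 2.37 for the G2/M list (37 of 46 members above 1) and 2.08 for the S phase list (39 of 42). The chromatin protein gene Hmgb2 had 1867 against 599 CPM and the replication gene Mcm6 226 against 65.6 CPM. Type 2 effector genes were lower, with a median of -0.92. Il1rl1 had 116 against 364 CPM and Il13 78.9 against 188 CPM, while Icos was close, at 605 against 663 CPM. The interferon response list had a median of -1.17. The clusters were cut from the same genes, so the differences describe how the clusters were divided.

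**Figure D1:**
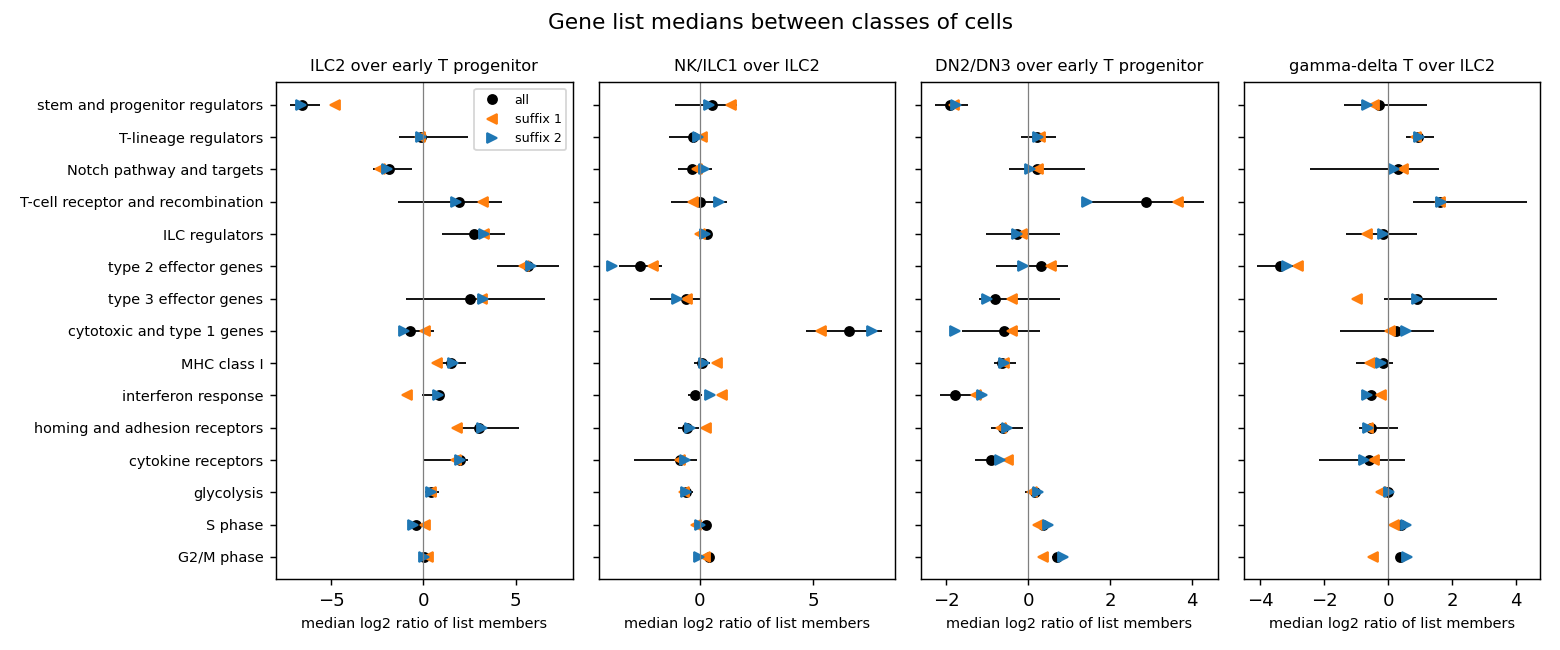
Median log2 ratio of the members of each gene list in 4 comparisons between classes, over all cells (black, with the interval of the median over members) and within each suffix (coloured). The interferon response list lies at -0.86 in suffix 1 and 0.79 in suffix 2 for ILC2-like over early T progenitor-like cells.

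The reporter locus genes differed between the classes. Gata3, Rora and Bcl11b are ILC2 markers and Bcl11b is a DN2/DN3 marker, so their levels in those classes partly restate the names. Id2 lies on chromosome 12 at 25093799 to 25097140, Gata3 on chromosome 2 at 9857078 to 9890034, Rora on chromosome 9 at 68653786 to 69388246 and Bcl11b on chromosome 12 at 107910403 to 108003602 (GRCm38). Id2, a repressor needed for ILC development, had 703 CPM in NK/ILC1-like, 359 CPM in ILC2-like and 16.7 CPM in early T progenitor-like cells. Rora had 187 CPM in ILC2-like, 81.2 CPM in gamma-delta T-like, 59.4 CPM in NK/ILC1-like and 2.33 CPM in early T progenitor-like cells. Bcl11b, a T commitment factor, had 436 CPM in alpha-beta thymocyte-like, 308 CPM in gamma-delta T-like, 171 CPM in DN2/DN3-like and 166 CPM in ILC2-like cells, against 7.98 CPM in NK/ILC1-like cells. Gata3 had 188 CPM in ILC2-like and 31.4 CPM in early T progenitor-like cells. After thinning each cell to 6970 UMIs, Rora was detected in 64.6% of ILC2-like cells (62.2 to 67.0%) and in 0.855% of early T progenitor-like cells (0.411 to 1.57%). Without thinning the shares were 80.9% at a median of 11624 UMIs and 4.55% at a median of 30742.5 UMIs. Over all cells with that depth, thinned detection was 59.8% for Id2, 37.1% for Gata3, 30.1% for Rora and 30.7% for Bcl11b.

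Summed per class, the reporter transcripts followed their locus genes to different degrees, which does not show that they did so cell by cell. After thinning, tagBFP was detected in 97.9% of ILC2-like cells with a UMI of its locus gene and 87.0% without. For hCD2 these shares were 46.7% and 33.9%, for TdTomato 5.19% and 2.66%, and for mTeal 32.6% and 32.3%. In NK/ILC1-like cells those of mTeal were 20.7% and 7.74%. The hCD2 row had 0.502 UMIs per Gata3 UMI in ILC2-like cells and 0.478 in early T progenitor-like cells. The TdTomato row had 0.0343 UMIs per Bcl11b UMI in ILC2-like and 0.0376 in DN2/DN3-like cells. The tagBFP row had 2.71 UMIs per Id2 UMI in ILC2-like cells (3.29 within suffix 1, 2.63 within suffix 2), 3.27 in NK/ILC1-like cells (3.56 and 2.79) and 7.70 in cluster 3. The mTeal row had 0.323 UMIs per Rora UMI in ILC2-like and 0.312 in NK/ILC1-like cells, and 0.463 in gamma-delta T-like and 0.693 in early T progenitor-like cells. It outnumbered Rora in DN2/DN3-like cells (59 against 3 UMIs), alpha-beta thymocyte-like cells (22 against 11) and cluster 3 (129 against 44).

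**Figure D2:**
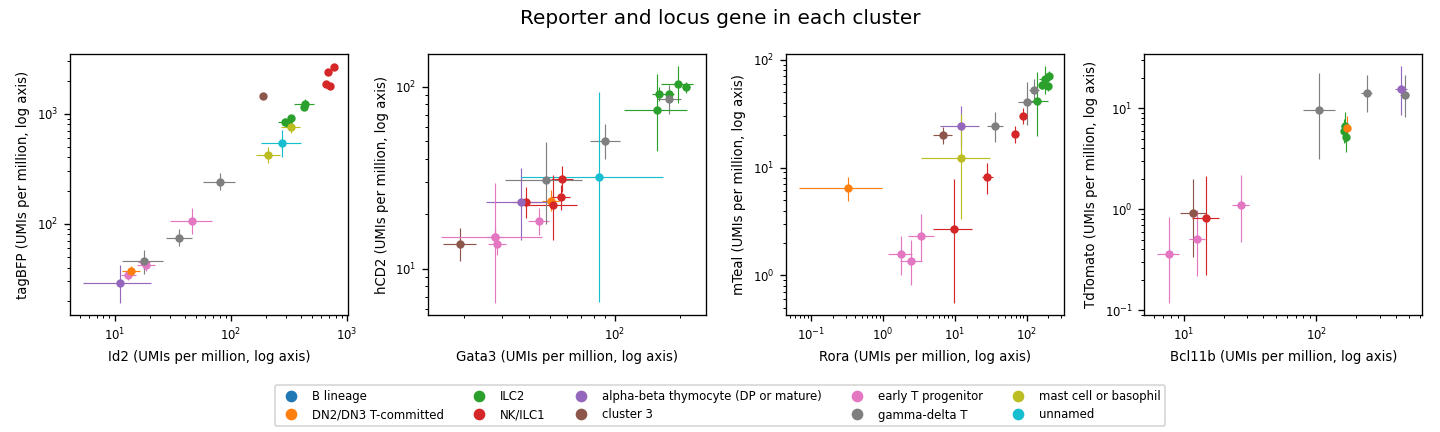
CPM of each reporter row (vertical, log axis) against its locus gene (horizontal, log axis) in each cluster with at least 3 UMIs of both, with 95% Poisson intervals. The DN2/DN3-like cluster lies at 6.40 CPM of mTeal and 0.326 CPM of Rora.

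G2/M transcripts were compared between classes as a measure of cycling. The summed list had a log2 ratio of 0.60 in DN2/DN3-like over early T progenitor-like cells, 0.35 in NK/ILC1-like over ILC2-like, 0.33 in gamma-delta T-like over ILC2-like and 0.14 in ILC2-like over early T progenitor-like cells. After thinning, the median G2/M UMIs per cell were higher in DN2/DN3-like than in early T progenitor-like cells within suffix 1 (55 against 48) and suffix 2 (74.5 against 24). In NK/ILC1-like against ILC2-like cells they were 65 against 45 within suffix 1 but 12 against 12 within suffix 2. In gamma-delta T-like against ILC2-like cells they were 45.5 against 45 and 25 against 12. The suffixes hold different ILC2-like clusters. Cluster 1, with a median of 10, had 6 cells of suffix 1 and 883 of suffix 2. Cluster 7, with 23, had 134 and 246, and cluster 8, with 131, had 101 and 270. ILC2-like cells had 13 against 32 in early T progenitor-like cells, opposite to the summed ratio of 0.14, and the G2/M list median fell below 0 in 7 alternatives, so no direction is given for that pair. Mki67 was detected after thinning in 64.9% of DN2/DN3-like, 54.4% of NK/ILC1-like (67.1% within suffix 1, 37.8% within suffix 2) and 33.8% of ILC2-like cells (52.5% and 30.8%). Without thinning the shares were 91.1%, 57.8% and 39.0%.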

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

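All tests in this part were chosen after the result was seen. Krt8, a keratin gene of epithelial cells, had 134 CPM in the barcodes of cluster 3 against 0.724 CPM in other kept cells, a signal in barcodes that the comparisons do not use. Krt18 had 223 against 5.91 CPM and Prss16, a protease gene of thymic cortical epithelium, 51.0 against 1.73 CPM. The same barcodes held the cytotoxic genes Nkg7 at 733 CPM against 392 CPM and Ccl5 at 885 against 279 CPM, while Gzmb, a granzyme gene, was lower at 28.1 against 42.4 CPM. Kept cells of suffix 1 outside cluster 3 had Nkg7 at 463 CPM and Ccl5 at 518 CPM. Part of these 2 differences thus goes with the suffix. Of the 555 barcodes, 553 were in suffix 1, where they were 25.9% of kept cells. The haemoglobin gene Hbb-bs had 40561 CPM in suffix 2 barcodes that failed the filters against 36.2 CPM in kept cells of suffix 2, also outside the comparisons. Hba-a1 had 15147 against 5.87 CPM.

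Free RNA in equal amounts in every droplet was not decided as the source of the epithelial transcripts. Cluster 3 was picked out by Krt8, a member of the thymic epithelium markers, so a low ratio to it was partly set in advance. Gzma in nearly all its barcodes was required as well, so a cytotoxic signal was also partly set in advance. Early T progenitor-like cells of suffix 1 had 0.182 times the thymic epithelium marker UMIs per barcode of cluster 3 (0.103 to 0.444, intervals here being bootstraps over barcodes). The tables argue against doublets of an NK/ILC1-like cell and an epithelial cell. The median UMIs of cluster 3 were 0.763 times those of NK/ILC1-like cells of suffix 1 (0.699 to 0.818). What also stays open is that the barcodes of cluster 3 may hold draws from 1 shared pool of RNA, such as that of lysed cells. With cells thinned to 1 depth, the spread of counts between barcodes was 1.03 times that of draws from 1 profile, against 1.09 to 1.28 in the other clusters of at least 50 cells. Among genes with a mean of at least 5 UMIs it was 1.10, against 1.28 to 1.90. No biological explanation was tested.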

How the results depend on the processing

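All alternatives for list medians and ratios between classes were chosen after the data were seen, while those for class shares and locus shares were mostly fixed beforehand. No paired analysis was possible because each sample has 1 library and the barcodes are not tied to samples. The stage comparisons and their scalings were not run for the same reason. The settings without cell filters, with doublets kept and with 1 suffix alone reused the main class of every kept cell, so they could not test the naming. In the other clusterings, a cluster made mostly of cluster 3 barcodes was kept unnamed by rule. The unnamed shares could therefore not test that choice. Of 2836 values under 23 settings, 2403 stayed within the set margin and 419 moved beyond it. A further 14, whose interval had excluded 0, changed sign, 0 of them under another scaling. Among all values 121 changed sign, 37 of them under another scaling. These include, for ILC2-like over early T progenitor-like cells, interferon genes in suffix 1 (-0.86), G2/M genes with the mean of each cell's CPM (-0.22) and ribosomal genes with TMM (0.079). At resolution 0.5 the share was B lineage 0%, DN2/DN3 4.51%. At resolution 2 the share was B lineage 0%, DN2/DN3 1.64%, ILC2 26.3%, alpha-beta thymocyte 2.16%, early T progenitor 19.9%, gamma-delta T 6.50%, unnamed 13.7%. With 4000 variable genes the share was B lineage 1.44%, DN2/DN3 1.66%, ILC2 26.2%, early T progenitor 19.53%, gamma-delta T 9.75%, unnamed 14.6%. With suffixes clustered apart the share was B lineage 0.739%, DN2/DN3 2.12%, ILC2 29.4%, gamma-delta T 5.63%. With reporter rows among the variable genes the share was B lineage 1.35%, ILC2 28.9%, gamma-delta T 7.07%, unnamed 10.2%. Without list members the share was B lineage 1.46%, DN2/DN3 2.46%, early T progenitor 18.9%, unnamed 14.4%. In suffix 1 the share was B lineage 0%, DN2/DN3 6.74%, ILC2 11.5%, NK/ILC1 34.6%, alpha-beta thymocyte 0%, early T progenitor 17.7%, gamma-delta T 0.935%, unnamed 27.4%. With stricter filters the share was DN2/DN3 4.62%. Without cell cycle genes the share was DN2/DN3 4.45%, early T progenitor 17.5%, unnamed 15.1%. With cluster 3 removed first the share was DN2/DN3 4.59%, ILC2 25.6%, NK/ILC1 26.7%, early T progenitor 23.97%, gamma-delta T 14.5%, unnamed 1.32%. In suffix 2 the share was DN2/DN3 1.77%, ILC2 45.4%, NK/ILC1 17.0%, alpha-beta thymocyte 2.56%, early T progenitor 24.6%, gamma-delta T 5.98%, unnamed 1.13%. Without cell filters the share was unnamed 13.7%. Median log2 ratios moved too. For ILC2-like over early T progenitor-like cells, suffix 1 gave -4.79 for stem regulators, 0.74 for MHC class I and 0.10 for S phase genes, the last with its direction changed. For NK/ILC1-like over ILC2-like cells, suffix 1 gave -0.14 for S phase and 0.29 for homing genes, and suffix 2 gave -0.036 for G2/M genes, all changed in direction, and -3.85 for type 2 genes. Without markers the 1 type 2 gene left gave -1.31 and cytotoxic genes 8.14. For DN2/DN3-like over early T progenitor-like cells, resolution 2 gave -2.57 for stem regulators and -0.081 for S phase genes, and 4000 variable genes gave -2.48 and -0.13, S phase changing direction in both. Stem regulators gave -2.40 without list members, interferon genes -2.43 with suffixes clustered apart, and the 1 T-cell receptor gene left without markers 0.50. Rora, with few UMIs, changed direction to 0.34 with stricter filters and 0.92 without cell cycle genes. For gamma-delta T-like over ILC2-like cells, T-lineage regulators gave 0.52 at resolution 2, 0.42 with 4000 variable genes and 0.33 with cluster 3 removed. G2/M genes changed direction to -0.43 with 4000 variable genes and -0.49 in suffix 1, where ribosomal genes (0.14) and mitochondrial genes (0.032) did too. For all of these the cause was not tested. Thinning to 2000 UMIs gave shares of 37.4% for Id2, 15.2% for Gata3, 13.4% for Rora and 14.2% for Bcl11b, by construction lower. The log2 ratio of cells with at least 2 G2/M UMIs was -0.0027, -0.00099, 0 and 0.0027 in the order ILC2-like over early T progenitor-like, NK/ILC1-like over ILC2-like, DN2/DN3-like over early T progenitor-like and gamma-delta T-like over ILC2-like, since nearly all cells pass. Other scalings shifted the median of all genes by 0.11 (median of ratios) and 0.12 (TMM) for ILC2-like over early T progenitor-like, by -0.14 for NK/ILC1-like over ILC2-like (totals without mitochondrial and ribosomal genes), and by -0.12 and -0.13 (median of ratios, TMM) for gamma-delta T-like over ILC2-like cells. For cluster 7 over cluster 1 the shifts were -0.12, -0.14 and -0.12 (median of ratios, TMM and totals without those genes).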

Other observations

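All tests in this part were chosen after the result was seen. Early T progenitor-like cells with a Rora UMI (54 of 1186) had Kit (80.6 CPM against 85.5 CPM in those without) and Flt3 (12.01 against 12.19 CPM), progenitor genes, at like levels. They had more Zbtb16, which encodes the ILC precursor factor PLZF (38.04 against 12.86 CPM), Icos (23.02 against 2.97 CPM), Id2 (31.5 against 15.9 CPM) and Cd163l1 (37.5 against 2.27 CPM). Zbtb16 was picked among many genes looked at.

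The log2 ratio of Zbtb16 in these cells was 1.56 (1.19 to 1.92), with 1.85 within suffix 1 and 1.31 within suffix 2. RNA of an ILC2-like, NK/ILC1-like or gamma-delta T-like cell cannot be told apart from expression: Zbtb16 needs 155.3 percentage points more ILC2-like RNA than the ILC2 markers do, but the interval widened for the genes it was picked from is -152.3 to 462.9. For Icos, Id2 and Cd163l1 such RNA also stays open. Icos, Id2 and Cd163l1 need 3.15%, 4.56% and 10.2% of ILC2-like RNA against 4.49% for the ILC2 markers (0.594 to 8.78%). They need 38.7%, 2.28% and 11.9% of NK/ILC1-like RNA against 2.03% for its markers (-0.689 to 5.77%). Of gamma-delta T-like RNA they need 53.3%, 80.4% and 11.2% against 9.02% for its markers (3.13 to 15.7%). Icos is itself in the ILC2 marker sum, and Icos and Cd163l1 are among the 4 gamma-delta T markers measured. Nearness of their shares to those of these markers was therefore partly set in advance. The shares of single genes have no interval, and that of Cd163l1 rests on 75 UMIs, so no class is excluded for these genes. Ccl5 (74.1 against 13.2 CPM, 148 UMIs in cells with a Rora UMI) needs 547% of ILC2-like, 4.31% of NK/ILC1-like and -1174% of gamma-delta T-like RNA. As they stand, ILC2-like or gamma-delta T-like RNA alone could not supply its level, while NK/ILC1-like RNA could. Ccl5 is itself an NK/ILC1 marker and was picked as the highest of many partner genes. Its shares therefore do not decide the source for the other genes. A property of any rarely detected gene also stays open: with each of 791 genes given its own best partner, Rora lay at percentile 78.1, with Ccl5, an NK/ILC1 marker, and not Zbtb16 as its partner (log2 ratio 2.49). No biological explanation was tested.

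In DN2/DN3-like cells 59 mTeal UMIs, in 47 of 202 cells, stood against 3 Rora UMIs. Free mTeal RNA in equal amounts would give early T progenitor-like cells without a Rora UMI a like level, but DN2/DN3-like cells had 8.06 times as many mTeal UMIs per barcode (5.32 to 12.3). That ratio pools the suffixes, with 144 of 202 DN2/DN3-like but 362 of 1132 comparison cells in suffix 1. DN2/DN3-like cells had 0.326 mTeal UMIs per barcode in suffix 1 and 0.207 in suffix 2. The comparison cells had 0.0362 over both suffixes, and no ratio within a suffix was computed. RNA of ILC2-like cells is argued against by mTeal per Rora that was 60.9 times that of ILC2-like cells (23.9 to 205). Reads of the Bcl11b reporter cassette counted as mTeal cannot be told apart from expression: within suffix 2, mTeal per Bcl11b in alpha-beta thymocyte-like over DN2/DN3-like cells was 2.25 with the Rora part and background taken off, with an interval of 0.822 to 7.35 set by few UMIs. Without that step it was 2.56 (1.32 to 5.81) within suffix 2 and 1.49 (0.861 to 2.40) over both suffixes, and DN2/DN3-like cells of suffix 1 over suffix 2 gave 2.09 (1.17 to 4.66), which a fixed ratio would not give, but the suffixes may differ as libraries.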
